A study of Mus musculus with 11 samples.

How the data were processed

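RNA from liver sinusoidal endothelial cells from 11 samples of mice was measured on Mouse Clariom S arrays, which carry probes over the length of known transcripts. Per the labels' protocols, total RNA was extracted with Trizol and biotin-labelled cDNA was made from 100 ng with a whole-transcript kit. Per the submitters' processing notes, the authors used Affymetrix Expression Console and RMA, with versions not given in the sources used here. RMA subtracts background, sets the distribution of probe values equal between arrays and summarizes the probes of a transcript cluster, so a change shared by most genes would be removed and weak signals are compressed. The deposited values are on the log2 scale, which was read from their range (2.15 to 13.79), and have 2 decimals. Scanner files were not used here, and scan dates were not known. How the cells were isolated or sorted, and the genome build, were not given in the sources used here, so no coordinates are printed.

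Arrays were put into 6 wild type and 5 knockout (titled autophagy deficient) from their titles, where each is a numbered biological replicate. The alleles are not in the titles: wild type is floxed Atg5 without Cre and knockout is floxed Atg5 with VE-cadherin Cre. The titles do not say that every replicate is a separate animal or a pool, so p-values measure the spread between these samples. Replicate numbers are shared between genotypes, but deviations of same-numbered arrays from their group means did not go together consistently, so the numbers were treated as names. Of the rows, 22206 transcript clusters were tested and 6640 control rows (spike-ins, antigenomic background, intron and exon controls) were left out. The platform's annotation gave 1 gene symbol for 19572 clusters, several for 0 and none for 2634, which are unnamed here. Symbols were checked through gene identifiers against a RefSeq gene table, and 0 changed. For the 55 symbols with more than 1 cluster the cluster brightest over all arrays was used. Some listed genes were not analysed here, and counts refer to the measured members.

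Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, genotype only) with Benjamini-Hochberg adjustment over all clusters at 0.05. Because the study's own rule takes a fold of at least 1.5 and an unadjusted p of at most 0.05 and names no test, the same limma fit was used for it. Single genes, list means and array measures were also tested with a two-sided exact permutation test over all 462 splits of the arrays, whose smallest p is 0.0022 for a value. Values are mean ± SD over arrays, and differences are knockout minus wild type on the log2 scale with limma's standard error. The 30 tested gene lists (autophagy, lysosome, inflammation, adhesion, interferon, antigen presentation, mesenchymal and matrix genes, death, stress, endothelial identity, metabolism, cell cycle and cell type markers) were written before the data were examined. They were tested with limma's camera at the preset correlation of 0.01 between genes, adjusted over the lists, and with an estimated correlation. Sex-linked genes served as a check only. For each list 0 members passed an adjusted p over all genes, and the number that passed adjusted over the list alone is given beside it.

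Genes to be named were fixed by a rule before the data were examined. They were Atg5, the 10 highest and 10 lowest clusters with a symbol (past an adjusted p of 0.05, filled up by the study's rule in order of p where fewer passed), up to 4 members of each list with the smallest p, and 13 genes of the study's themes whatever their value. Predicted genes, olfactory and vomeronasal receptors and sex-linked genes were left out of the ranking. As 0 clusters passed the adjusted p, both sets of 10 were those of smallest p by the study's rule, not those of largest difference. Tests were tried on simulated arrays with the real means and variances and with noise drawn independently for each cluster. In the real arrays the clusters vary together (41.3% of the variance on the first principal component), so these shares need not hold there. Of 67 clusters changed by 0.58 on the log2 scale, 35.8% passed an adjusted p of 0.05 and 38.8% the study's rule. Of 67 changed by 1, 83.6% and 97.0% did. Of 66 changed by 2, 97.0% and 100% did. Among the unchanged clusters 5 passed the adjusted p and 181 the study's rule. Alternatives covered each array left out, a replicate block, repeated quantile normalization, median centring, array weights, list means of hepatocyte and macrophage genes as covariates, other variance models, filters on dim clusters, other thresholds and other list tests (fry and the mean of all clusters of a symbol). After the data were seen, sex, the intron controls, both list means together, leaving out 4 arrays and a permutation test of list means were added.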

Results

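Gene expression was measured in liver sinusoidal endothelial cells (LSEC), the fenestrated endothelium that lines the hepatic capillaries, from mice put on high fat chow at 8 weeks of age and sampled 2 weeks later. The wild type mice carried floxed Atg5 alleles without Cre (6 arrays). The knockout mice carried the same alleles with a Cre recombinase under the VE-cadherin promoter, which is active in endothelial cells (5 arrays). Atg5 encodes a protein needed for autophagosome formation. The question was how loss of endothelial autophagy changes the LSEC transcriptome early in high fat feeding, with inflammation and fibrosis as the themes of the study. Each array was labelled as a separate biological replicate. A total of 22206 transcript clusters were compared on the log2 scale, with array medians between 6.61 and 6.75. The number of arrays limits the precision.

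Atg5 itself was not lower in the knockout arrays. Its log2 level was 7.50 ± 0.09 (SD, n = 6) in wild type and 7.60 ± 0.17 (SD, n = 5) in knockout, a difference of 0.10 (SE 0.10) with an exact permutation p = 0.245. Knockout array 4 read 7.90 and the other knockout arrays read between 7.48 and 7.57. Where the probes lie relative to the floxed part of the gene is not known here, so this level does not check the genotype, and every direction below follows the labels. The other autophagy genes lay slightly higher as a list of 37 core factors and receptors, with a median log2 difference of 0.11 and 32 of 37 above 0. No member met the study's rule of a fold of at least 1.5 with an unadjusted p of at most 0.05, and 0 passed adjusted over the list alone. The receptor Sqstm1 (0.05, SE 0.15) and the autophagosome marker Map1lc3b (0.04, SE 0.10) differed by less than the spread between arrays, and both turned sign with some arrays left out. The members of smallest p were Pik3c3, the lipid kinase of autophagosome nucleation (0.30, SE 0.16), and Atg13 (0.22, SE 0.12). Against the other genes the list passed camera with the preset correlation (adjusted p = 0.0018), and the call was lost with an estimated correlation (adjusted p = 0.298). Over 26 alternatives its adjusted p ran from 0.00041 to 0.298, and without wild type array 5 its median was 0.06. The call was also lost with the hepatocyte marker mean as a covariate (adjusted p = 0.057) or with the hepatocyte and macrophage means together (0.110). With the macrophage mean alone the adjusted p was 0.047.

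Of 25 listed cytokines and chemokines, 8 were higher in the knockout arrays by the study's rule. Il6 averaged 8.56 ± 0.43 (SD, n = 5) in knockout and 7.08 ± 0.87 (SD, n = 6) in wild type, a 2.8-fold difference with an exact permutation p = 0.015. The monocyte chemoattractants Ccl2 and Ccl7 were 1.72-fold and 1.92-fold higher, from wild type levels of 11.23 ± 0.33 and 8.37 ± 0.35 (SD, n = 6), with exact permutation p = 0.0087 and 0.0065. The T cell chemoattractant Ccl5 was 1.89-fold higher (log2 difference 0.92, SE 0.27) and the neutrophil chemoattractant Cxcl2 1.61-fold higher (0.69, SE 0.19). All 5 knockout arrays lay above the wild type mean for each of these genes. Of the 25 genes 21 lay above 0 and 4 below, with a median of 0.19, and none was lower by the rule. In the limma fit 7 passed adjusted over the list alone and 0 passed over all genes, where these 5 genes had an adjusted p of 0.76. The list passed camera with the preset correlation (adjusted p = 6.0e-09) but not with an estimated correlation (adjusted p = 0.298). Wild type array 5 had the highest list mean of its group, 9.43 against 8.80 to 8.97 in the others, and without it the list median was 0.36. The median was 0.32 without knockout array 1 and 0.34 without knockout array 4, and over 26 alternatives the adjusted p ran from 6.5e-13 to 0.298. With the macrophage marker mean as a covariate the adjusted p of the list was 0.161. Without knockout array 1, Cxcl2 no longer met the rule (0.57).

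**Figure D1:**
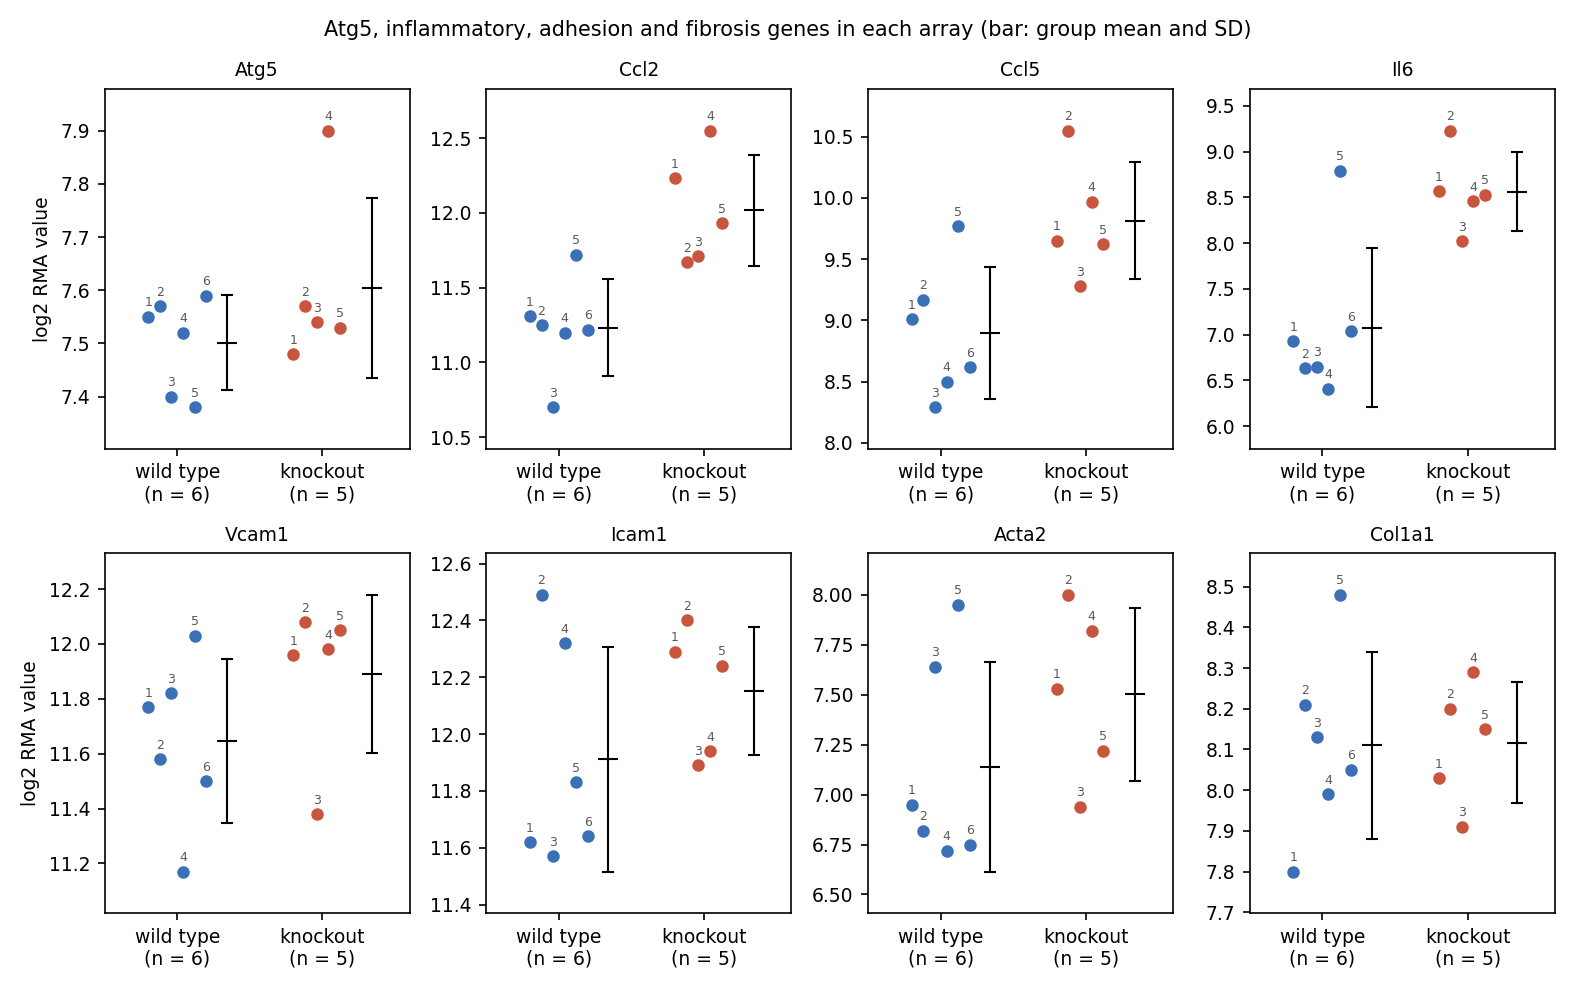
Log2 level (vertical axes) of 8 genes in each of 6 wild type (blue) and 5 knockout (red) arrays, numbered by replicate, with the group mean and SD as bars. The knockout mean was higher by 0.78 for Ccl2, 0.92 for Ccl5 and 1.49 for Il6, and by 0.25 or less for Atg5, Vcam1, Icam1 and Col1a1.

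Other immune signalling genes stood among the 10 clusters named as higher in knockout by the fixed rule, which were those of smallest p. Il10, an anti-inflammatory cytokine, was 2.97-fold higher (log2 6.63 ± 0.61 in wild type, SD, n = 6, and 8.20 ± 0.68 in knockout, SD, n = 5, exact permutation p = 0.0065). The costimulatory receptor Cd86 was 2.14-fold higher and the endosomal RNA sensor Tlr7 2.47-fold higher. Adgre4, an adhesion receptor of macrophages, was 2.56-fold higher. Macrophage markers were higher in the same arrays (median 1.10). With their mean as a covariate, 16 of the 33 named genes called by the rule were still called, 16 were not and 1 turned. With the macrophage and hepatocyte means together 4 were, 23 were not and 6 turned. The 33 include Vsig4, Spic, Folr2 and Aif1 of the macrophage list and Serpina1a, Rbp4, Serpina1b and Apoa2 of the hepatocyte list. A loss of these under their own list's mean is in part by construction, and the counts do not tell which genes kept the call. Rasa3, a GTPase-activating protein, and the transcription factor Tbx20 were higher by 0.60 and 0.68 on the log2 scale. Rasa3 fell below a fold of 1.5 without knockout array 2 (log2 0.52), knockout array 4 (0.57) or wild type array 4 (0.55). Of 17 NF-kB feedback genes and targets, 16 lay above 0 with a median of 0.15. The TNF-induced gene Tnfaip2 met the rule (0.71, SE 0.26), which it did not without knockout array 2 (0.55). Cd40 (0.50, SE 0.15) and the inhibitor Tnfaip3 (0.23, SE 0.10) were higher by less than 1.5-fold. None of the 17 passed adjusted over the list alone. The list passed camera with the preset correlation (adjusted p = 0.00012), not with an estimated correlation (adjusted p = 0.298), and over 26 alternatives its adjusted p ran from 1.7e-06 to 0.443, the highest with the macrophage marker mean as a covariate (median -0.007). All 15 antigen presentation genes lay above 0 (median 0.16), and the MHC class II genes H2-Aa (0.78, SE 0.41) and H2-DMb1 (0.90, SE 0.49) had the smallest p, but none met the rule or passed adjusted over the list alone. Both genes met the rule without wild type array 5 (0.98 and 1.11) or knockout array 3 (1.08 and 1.24). This list had an adjusted p of 0.00027 with the preset and 0.505 with an estimated correlation, and without knockout array 2 its median was 0.08 and its adjusted p with the preset correlation was 0.070. Its median was 0.10 without wild type array 6 and 0.29 without knockout array 4, and over 26 alternatives the adjusted p ran from 3.2e-09 to 0.923. Macrophage markers were higher in the same arrays, and with their mean as a covariate the median turned to -0.30 (camera direction lower, adjusted p = 0.273). Of 28 interferon-stimulated genes 20 lay above 0 (median 0.15), with Oas3 at 0.26 (SE 0.11) and Mx1 at 0.54 (SE 0.31), and 0 met the rule or passed adjusted over the list alone. Oas3 read below the array's own antigenomic background mean in all 11 arrays, so its difference says nothing of expression. Mx1 met the rule without wild type array 5 (0.70). That list had an adjusted p of 0.0048 with the preset and 0.488 with an estimated correlation. The first was lost without knockout array 2 (adjusted p = 0.055, median 0.09) or wild type array 4 (0.075, median 0.08). Over 26 alternatives the adjusted p ran from 2.8e-05 to 0.597, the highest from fry, which tests a list against no change. With the macrophage marker mean as a covariate the median was -0.008 (adjusted p = 0.331).

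Macrophage markers lay farthest above 0 of the 30 lists. All 18 measured Kupffer cell and macrophage genes lay above 0, with a median log2 difference of 1.10, 14 met the study's rule and 13 passed adjusted over the list alone. Vsig4, a complement receptor of Kupffer cells, was 3.13-fold higher (7.70 ± 0.72 in wild type, SD, n = 6, and 9.35 ± 0.86 in knockout, SD, n = 5, exact permutation p = 0.011). The folate receptor Folr2 was 2.9-fold, the macrophage gene Aif1 2.96-fold and Spic, a transcription factor of red pulp and iron-handling macrophages, 2.53-fold higher. Aif1 read below the array's own antigenomic background mean in 4 of 6 wild type arrays, so its fold is not a measured ratio of expression. The mean of the 18 genes was 7.51 ± 0.44 (SD, n = 6) in wild type and 8.59 ± 0.86 (SD, n = 5) in knockout, with an exact permutation p = 0.017 that came to 0.16 after adjustment over the 30 lists. Camera gave an adjusted p of 3.1e-15 with the preset correlation. It gave an adjusted p of 0.298 with an estimated correlation. Over 26 alternatives the adjusted p ran from 3.0e-24 to 0.948, the highest with the list's own mean as a covariate. After subtraction of the group means, the mean of the called cytokine genes followed the macrophage mean over 11 arrays (Pearson r = 0.831, permutation p = 0.0036; Spearman rho = 0.527, permutation p = 0.099). Without the 2 arrays farthest from the median r was 0.512, so the relation rests on these arrays. Knockout array 2 had the highest macrophage mean (9.95) of the 11 arrays and wild type array 5 the highest of its group (8.32). Across leave-one-out fits the median of the macrophage list stayed between 0.73 and 1.39.

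Hepatocyte transcripts were lower in the knockout arrays. All 22 measured hepatocyte markers lay below 0, with a median log2 difference of -0.93, 15 met the study's rule and 9 passed adjusted over the list alone. The antitrypsin gene Serpina1a was 2.3-fold lower (11.10 ± 0.40 in wild type, SD, n = 6, and 9.90 ± 0.69 in knockout, SD, n = 5, exact permutation p = 0.0065). The retinol carrier Rbp4 was 2.05-fold and the apolipoprotein Apoa2 1.99-fold lower. The list mean was 9.35 ± 0.58 (SD, n = 6) in wild type and 8.47 ± 0.64 (SD, n = 5) in knockout, with an exact permutation p = 0.043 and an adjusted p of 0.23 over the 30 lists. Camera gave an adjusted p of 4.0e-15 with the preset correlation. It gave an adjusted p of 0.298 with an estimated correlation, and over 26 alternatives from 2.2e-25 to 0.995, the highest with the list's own mean as a covariate. By the fixed rule, the 10 clusters named as lower in knockout were those of smallest p, not of largest difference. They were Fah of tyrosine breakdown, Aspdh, Serpina1a, Serpina1c, Serpina1d, Serpina10, Rbp4, Nat8f2, the glucuronosyltransferase Ugt2b5 and the canalicular exporter Abcc2. Ugt2b5 read below the array's own antigenomic background mean in 4 of 5 knockout arrays, so its size of difference is uncertain. The log2 differences of the 10 ran from -1.20 to -0.59, with exact permutation p from 0.0022, the smallest that the 462 splits can give, to 0.030. The Serpina1 genes are close copies, and whether their probes separate them was not checked. Fah and Abcc2 fell below a fold of 1.5 without wild type array 5 (-0.50) and wild type array 1 (-0.54), and Aspdh without wild type array 2 (-0.55) or 5 (-0.52) or knockout array 1 (-0.57) or 2 (-0.49).

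**Figure D2:**
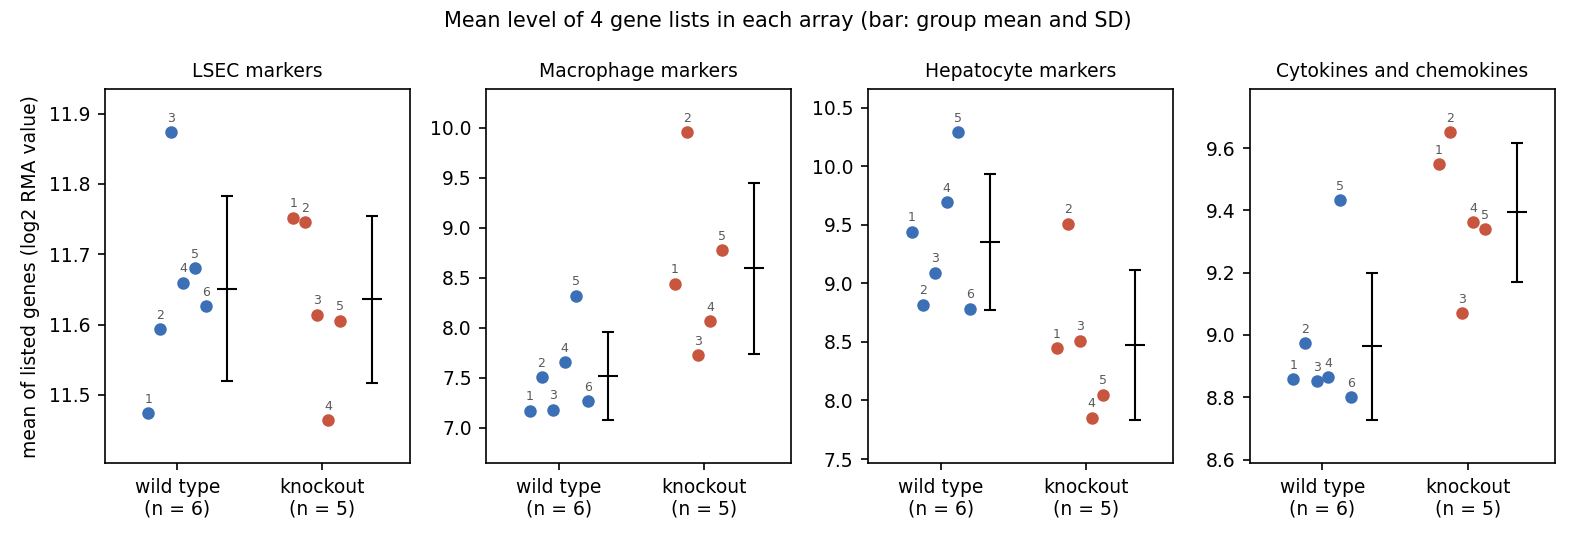
Mean log2 level (vertical axes) of the listed LSEC, macrophage, hepatocyte and cytokine genes in each of 6 wild type (blue) and 5 knockout (red) arrays, numbered by replicate, with the group mean and SD as bars. LSEC markers averaged 11.65 in wild type and 11.64 in knockout, macrophage markers 7.51 and 8.59, hepatocyte markers 9.35 and 8.47, and cytokines 8.96 and 9.39.

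The 19 LSEC markers had a median of -0.04 and a list mean of 11.65 ± 0.13 (SD, n = 6) in wild type and 11.64 ± 0.12 (SD, n = 5) in knockout, with an exact permutation p = 0.848. The hyaluronan receptor Lyve1 differed by 0.27 (SE 0.18), the lectin Cd209b by 0.34 (SE 0.19) and the VEGF receptor Kdr by -0.12 (SE 0.12). The LSEC median ran from -0.075 without knockout array 2 to -0.006 without knockout array 4. The pan-endothelial cadherin Cdh5, whose promoter drove Cre, read 12.54 ± 0.04 (SD, n = 6) and 12.55 ± 0.13 (SD, n = 5). Neither the 10 pericentral genes (median -0.09, with Thbd at -0.27, SE 0.18, and Vwf at -0.51, SE 0.35) nor the 10 periportal genes (median 0.09, smallest p for Efnb1 at 0.35, SE 0.19) passed camera (adjusted p = 0.372 and 0.25). The pericentral median was -0.16 without knockout array 2 and turned to 0.03 without wild type array 3, and the periportal median turned to -0.003 without wild type array 5. The 17 genes of continuous and large-vessel endothelium, Vwf among them, had a median of 0.004 and a mean of -0.004, and camera placed them higher with an adjusted p of 0.891. This median ran from -0.05 without wild type array 1 to 0.07 without wild type array 2, and was also below 0 without wild type array 6 or knockout array 2. No gene of these 4 lists met the rule or passed adjusted over the list alone, except Vwf by the rule once wild type array 6 was left out (-0.72). Among 20 vasoactive and haemostatic genes the median was 0.02 (camera adjusted p = 0.196), and 2 met the rule. The median was below 0 without wild type array 6 (-0.03) or knockout array 1 (-0.03) or 2 (-0.004) and highest without wild type array 4 (0.075). The list passed with the hepatocyte mean as a covariate (adjusted p = 0.021, against 0.021 to 0.919 over 26 alternatives). Ptgs2, the inducible cyclooxygenase, was 2.52-fold higher (exact permutation p = 0.017, n = 6 and 5). Arg2, which breaks down arginine, was 1.71-fold higher with an exact permutation p = 0.108. Its call was lost without any one of 8 of the 11 arrays, with a lowest log2 difference of 0.52 without knockout array 2. Macrophage markers were higher in the same arrays, and with their mean as a covariate Arg2 turned to -0.05. Neither passed adjusted over the list alone. The endothelial nitric oxide synthase Nos3 differed by -0.03 (SE 0.28).

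Adhesion and fibrosis genes did not meet the study's rule. The adhesion molecules Vcam1 (0.25, SE 0.17) and Icam1 (0.24, SE 0.18) were each above the wild type mean in 4 of 5 knockout arrays, with exact permutation p = 0.197 and 0.251. Of 15 leukocyte adhesion genes, 8 lay above 0, the median was 0.04 and camera gave an adjusted p of 0.377. The median ran from 0.02 without wild type array 2 to 0.11 without wild type array 3. Smooth muscle actin Acta2 (0.36, SE 0.26), the collagens Col1a1 (0.01, SE 0.13) and Col1a2 (0.30, SE 0.24) and Tgfb1 (0.12, SE 0.12) differed by less than the spread between arrays, and Col1a1 turned sign with some arrays left out. Over 27 genes of mesenchymal transition and TGF-beta response, 20 lay above 0 with a median of 0.12 and the smallest p for Tagln (0.57, SE 0.37). Its adjusted p was 0.044 with the preset and 0.556 with an estimated correlation. That call was lost on leaving out any one of 7 arrays, namely wild type arrays 1 (adjusted p = 0.167), 4 (0.075) and 6 (0.195) and knockout arrays 1 (0.052), 2 (0.132), 4 (0.115) and 5 (0.073), and over 26 alternatives the adjusted p ran from 0.0022 to 0.8005. Over 14 basement membrane genes the median was 0.13. The laminin Lamc1 (0.29, SE 0.10) had the smallest p, and the laminin Lamb1 differed by 0.59 (SE 0.37). The list had an adjusted p of 0.044 with the preset and 0.615 with an estimated correlation. That call was lost without wild type array 1 (0.301) or 6 (0.242) or knockout array 2 (0.469) or 5 (0.073), with medians of 0.05 and 0.08 for the wild type arrays and 0.06 for knockout array 2. Over 26 alternatives its adjusted p ran from 0.0029 to 0.706, the highest from fry, which tests a list against no change. With the macrophage marker mean as a covariate the medians of the last 2 lists turned to -0.13 and -0.11 (camera direction lower, adjusted p = 0.8005 and 0.547). None of these 3 lists had a member past adjustment over the list alone.

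Stellate cell markers lay higher as well, with 12 of 13 above 0 and a median of 0.39. The collectin Colec10 met the rule (0.64, SE 0.24) and the retinol esterifying enzyme Lrat, typical of stellate cells, stood at 0.52 (SE 0.28), which met the rule without wild type array 5 (0.66). The list had an adjusted p of 0.00054 with the preset and 0.472 with an estimated correlation, and without knockout array 2 its median was 0.22 and Colec10 no longer met the rule (0.54). Colec10 also lost it without wild type array 3, 4 or 5 or knockout array 4 (0.51 to 0.58). Over 26 alternatives the adjusted p of the list ran from 1.1e-07 to 0.794. Macrophage markers were higher in the same arrays, and with their mean as a covariate the stellate median turned to -0.13 (camera direction lower, adjusted p = 0.794). With the macrophage and hepatocyte means as covariates, a fit chosen after seeing the data in which the difference of these means separates the genotypes, it was -0.71 (direction lower, adjusted p = 0.00047). Cholangiocyte markers lay lower, with 7 of 9 below 0 and a median of -0.23 and the smallest p for Sox9 (-0.48, SE 0.16) and the keratin Krt18 (-0.44, SE 0.15). The adjusted p was 0.0042 with the preset and 0.472 with an estimated correlation, and without knockout array 2 the median was -0.34. Hepatocyte markers were lower in the same arrays (median -0.93), and with their mean as a covariate the adjusted p was 0.140. Over 26 alternatives the adjusted p ran from 2.4e-05 to 0.472. All 9 platelet and erythroid markers lay below 0 (median -0.15), with the smallest p for Klf1 (-0.32, SE 0.10) and an adjusted p of 0.019 with the preset and adjusted p of 0.298 with an estimated correlation. Over 26 alternatives it ran from 0.012 to 0.298. Without knockout array 2 or wild type array 6 the first became 0.055 and 0.071. It was also lost with the macrophage (0.273) or hepatocyte (0.056) marker mean as a covariate, and with both (0.215). The other blood cell lists did not pass camera on all arrays. Monocyte and neutrophil markers had a median of -0.04 against a mean of 0.007 and a camera direction of higher (adjusted p = 0.947), lymphocyte markers a median of 0.09 (0.330) and dendritic cell markers a median of -0.07 (0.737). With an array left out these medians ran from -0.23 (without knockout array 1) to 0.15 (without knockout array 3), from -0.03 (without knockout array 1) to 0.15 (without knockout array 4) and from -0.14 (without knockout array 4) to -0.02 (without wild type array 1). The first was above 0 without wild type array 3, 4 or 5 or knockout array 3 or 5, and the second below 0 without knockout array 1 or 2. The call for monocyte and neutrophil markers appeared only when knockout array 1 was left out, as lower (adjusted p = 0.023, against 0.023 to 0.999 over 26 alternatives). Lymphocyte markers passed as higher without the 4 arrays of highest intron signal (0.016) and with the hepatocyte mean as a covariate (0.043), against 0.016 to 0.9996 over 25 alternatives. None of these 6 lists had a member past adjustment over the list alone.

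Among stress and death genes, the mean of the 20 pro-apoptotic genes was 8.04 ± 0.03 (SD, n = 6) in wild type and 8.15 ± 0.04 (SD, n = 5) in knockout. All 5 knockout arrays lay above all 6 wild type arrays, with an exact permutation p = 0.0043, the smallest of the 30 lists, which was 0.13 after adjustment over them. Bid, a pro-apoptotic BH3 protein, was 1.4-fold higher (6.40 ± 0.20 in wild type, SD, n = 6, and 6.89 ± 0.16 in knockout, SD, n = 5, exact permutation p = 0.0022, the smallest possible). It was the 1 of 20 pro-apoptotic genes past adjustment over the list alone, and the list had a median of 0.06 and a camera adjusted p of 0.051, which was under the threshold on leaving out wild type array 2 or 4 or knockout array 4 (0.020, 0.040 and 0.023). The median was 0.009 without knockout array 1 and 0.11 without knockout array 3, and the list passed in 5 of 26 alternatives (adjusted p from 0.020 to 0.557). Its camera adjusted p was 0.440 with the mean of the macrophage markers, also higher in knockout, as a covariate. The 22 NRF2 targets (median 0.11, camera adjusted p = 0.077) and the 22 genes of the unfolded protein and integrated stress response (median 0.03, 0.113) had no member by the rule. Their members of smallest p were the exporter Abcc1 (0.44, SE 0.23) and Sesn2 (0.46, SE 0.22), which met the rule without wild type array 4 (0.60). Both lists passed camera without knockout array 1 (adjusted p = 0.0093 and 0.023), and on all arrays had an adjusted p of 0.660 and 0.505 with an estimated correlation. NRF2 targets also passed without wild type array 1 (0.0069) or 6 (0.011) or knockout array 2 (0.0098), and the stress response list without wild type array 4 (0.040) or knockout array 5 (0.044). With the macrophage marker mean as a covariate NRF2 targets passed as higher (0.00032), as they did with array weights (0.0019) and both list means as covariates (0.031). They also did with the replicate block (0.031), a fit that leaves out wild type array 6. The stress response also passed with both list means (0.012). Over 26 alternatives 8 and 4 calls were made, with adjusted p from 0.00032 to 0.752 for NRF2 targets and from 0.012 to 0.789 for the stress response. The 0.752 came from fry, which tests a list against no change. The NRF2 median was 0.03 without knockout array 4 and 0.20 without knockout array 2, and the stress response median -0.003 without knockout array 3 and 0.12 without knockout array 5. The 20 immediate early and dissociation stress genes had a median of -0.03 (camera adjusted p = 0.737), with the heat shock gene Hspa1b at -0.53 (SE 0.36), which met the rule without wild type array 5 (-0.79). That median was -0.13 without knockout array 1 and above 0 without wild type array 2 (0.03) or 4 (0.015) or knockout array 4 (0.015).

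Metabolic, lysosomal and growth lists had medians near 0. Insig1, which holds back sterol synthesis, was 1.5-fold higher (exact permutation p = 0.0065, n = 6 and 5) and the 1 of 18 cholesterol synthesis genes past adjustment over the list alone. The list median was 0.05 and camera gave an adjusted p of 0.372. The median was below 0 without wild type array 1 (-0.03) or 2 (-0.05) or knockout array 1 (-0.02) or 2 (-0.07), and 0.08 without knockout array 4. Insig1 lay at the fold threshold and missed it without any one of 5 arrays (lowest 0.51 without wild type array 4). The 25 genes of fatty acid handling had a median of 0.01 (camera adjusted p = 0.197), with the smallest p for the beta-oxidation enzyme Hadhb (0.28, SE 0.12), and the list passed without knockout array 4 (adjusted p = 0.046, median 0.11) and with the hepatocyte mean as a covariate (0.0016), against 0.0016 to 0.963 over 26 alternatives. Its median was below 0 without wild type array 1 (-0.02) or 6 (-0.07) or knockout array 1 (-0.02) or 2 (-0.05). Over 28 lysosomal genes the median was 0.08, with the master regulator Tfeb lower (-0.28, SE 0.10) and the cholesterol transporter Npc1 higher (0.39, SE 0.15). Over 20 oxidative phosphorylation genes it was 0.07, with Uqcrfs1 at 0.25 (SE 0.11) and Ndufa9 at 0.42 (SE 0.19). Over 22 cell cycle genes it was 0.05, with Mcm6 (0.52, SE 0.16) and Mki67 (0.53, SE 0.17) of smallest p, while Bub1b met the rule (0.67, SE 0.28). These 3 lists had adjusted p of 0.019, 0.0099 and 0.019 with the preset correlation. With an estimated correlation the adjusted p were 0.505, 0.653 and 0.634. All 3 turned to a median below 0 without knockout array 2, at -0.009, -0.01 and -0.08, where their adjusted p were 0.428, 0.453 and 0.962. All 3 were also lost without wild type array 1 (0.071, 0.133 and 0.059) or 6 (0.111, 0.111 and 0.069), and the first 2 without knockout array 1 (0.052 and 0.066). The oxidative phosphorylation mean was 8.79 to 9.02 in wild type arrays 1 and 6 and knockout arrays 3 and 4, and 9.16 to 9.60 in the others. With other arrays left out the medians stayed at or below 0.13, 0.17 and 0.11, each highest without knockout array 4. Over 26 alternatives the adjusted p ran from 0.00012 to 0.706, from 1.9e-06 to 0.923 and from 1.9e-06 to 0.962. The 0.706 came from fry, which tests a list against no change. With the macrophage marker mean as a covariate the 3 medians turned to -0.20, -0.23 and -0.20 (camera direction lower, adjusted p = 0.630, 0.273 and 0.331). Bub1b lost the rule without wild type array 1 or 5 or knockout array 1 or 2 (lowest 0.37 without the last). Mcm6 gained it without wild type array 1 (0.60) or knockout array 4 (0.59), and Mki67 without wild type array 5 (0.59). Besides Insig1, 0 genes of these 5 lists passed adjusted over the list alone.

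**Figure D3:**
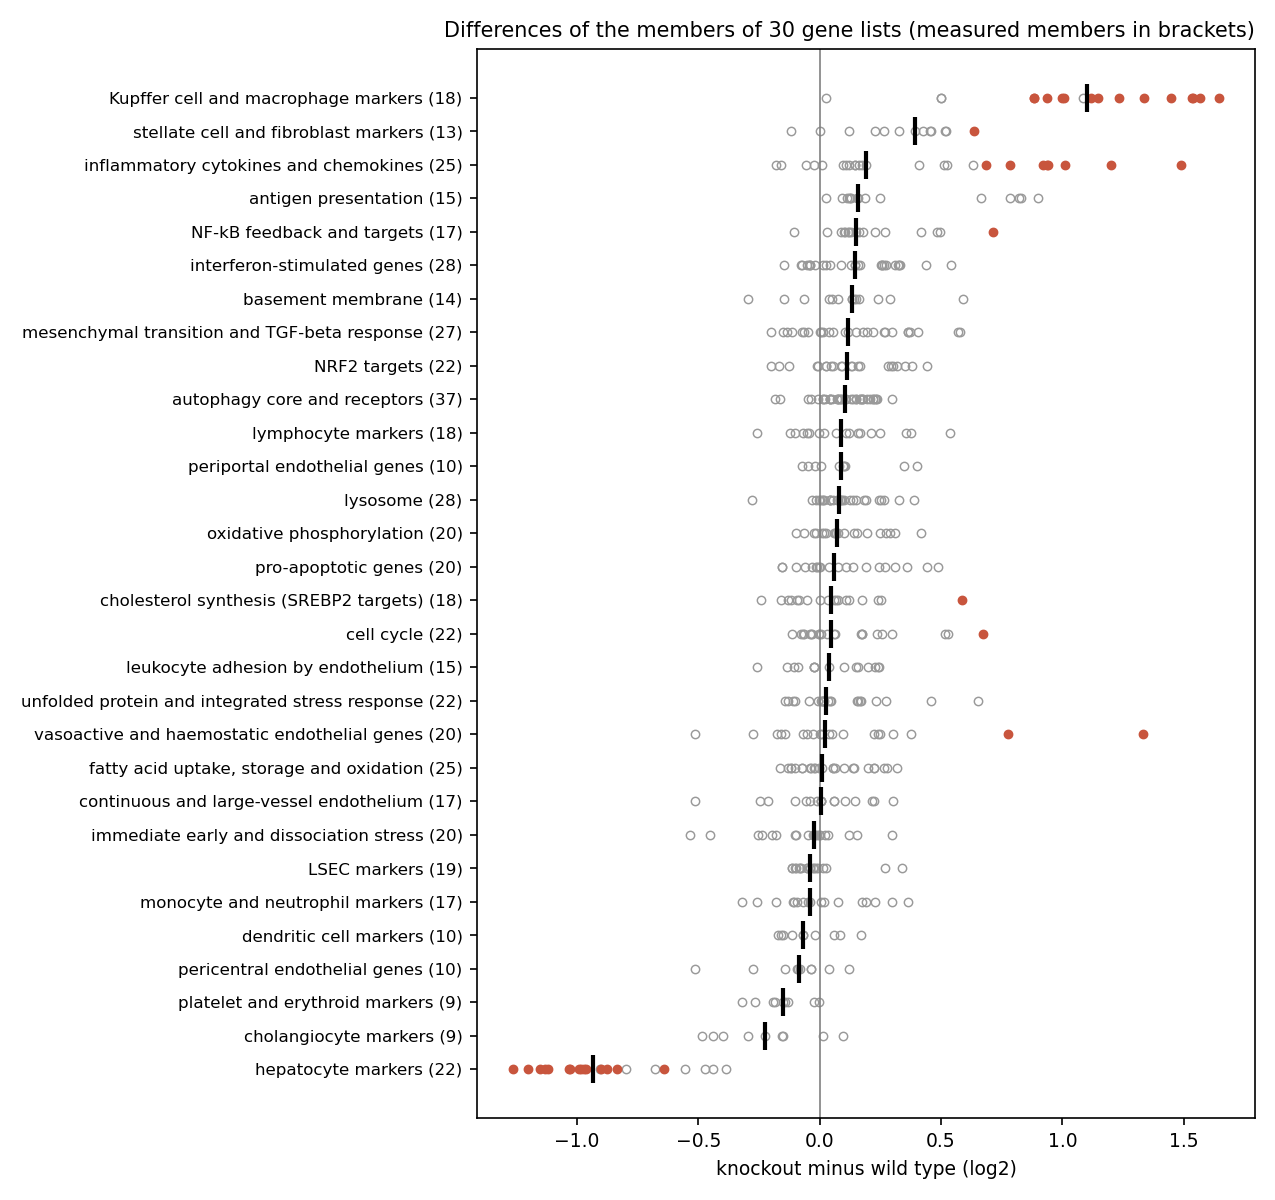
Log2 difference of knockout minus wild type (horizontal axis) for each measured member of 30 gene lists, with members that met the fold and p rule filled red and list medians as black bars. Macrophage markers (median 1.10) and hepatocyte markers (median -0.93) lay farthest from 0, and the red members of the cytokine list stood apart from its median of 0.19.

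Over all transcript clusters, 228 met the study's rule, 149 higher and 79 lower in knockout, of which 138 and 72 had a gene symbol. The rule uses unadjusted p-values, and 0 clusters passed an adjusted p of 0.05 in the limma fit (smallest adjusted p 0.765), with its variance moderation turned off or with an intensity trend and robust variance. Without wild type array 5 there was 1. At an unadjusted p under 0.05 there were 1419 clusters, 579 higher and 840 lower, where chance alone gives 1110.3. All values of the genotypes were separate for 105 clusters (0.473%), and chance gives 0.433%. The balance of directions depended on single arrays and on their weights. With array weights from limma there were 99 higher and 146 lower clusters. Without knockout array 2 there were 125 higher and 138 lower clusters, and without wild type array 5 there were 224 and 37. Without knockout array 3 there were 245 higher, and without wild type array 4 or knockout array 1, 4 or 5 there were 50, 48, 40 and 38 lower clusters. Of the 30 lists 15 passed camera with the preset correlation and 0 with an estimated one, and 8 passed without knockout array 2 and 10 without wild type array 6.

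The arrays did not group by genotype. Ward clustering on all clusters put 2 wild type and 3 knockout arrays in one branch and 4 and 2 in the other, so 7 of 11 arrays went with their genotype. The first principal component held 41.3% of the variance and did not separate the genotypes (exact permutation p = 0.753, n = 6 and 5), nor did the second, with 16.7% (exact permutation p = 0.078, n = 6 and 5). The first followed the mean of the intron control probe sets, which should stay dark for spliced RNA (Pearson r = -0.953, permutation p = 4e-05; Spearman rho = -0.936, permutation p = 5e-05; 11 arrays). After Benjamini-Hochberg adjustment over 5 such relations p was 1e-04, and r was -0.946 without the 2 arrays farthest from the median. The arrays fall into 7 of lower and 4 of higher intron signal, and within the 7 r was -0.895 (exact permutation p = 0.014) and rho -0.786 (exact permutation p = 0.048), with r = -0.895 again without the 2 farthest. The intron control mean lay between 5.75 and 5.96 in wild type arrays 1 and 6 and knockout arrays 3 and 4, and between 5.05 and 5.38 in the other 7. It did not differ between genotypes (exact permutation p = 0.840, n = 6 and 5). Without these 4 arrays 359 clusters met the study's rule and 0 passed an adjusted p of 0.05. Both sexes were present: the mean of 3 Y-linked genes was 8.17 and 8.51 in wild type arrays 3 and 6 and 8.02 in knockout array 3, and at most 3.79 in the others. With sex as a covariate 132 clusters were higher and 96 lower by the study's rule. The camera calls were then lost for lysosome and cell cycle (adjusted p = 0.051 each) and for mesenchymal transition and basement membrane (0.081 each).

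**Figure D4:**
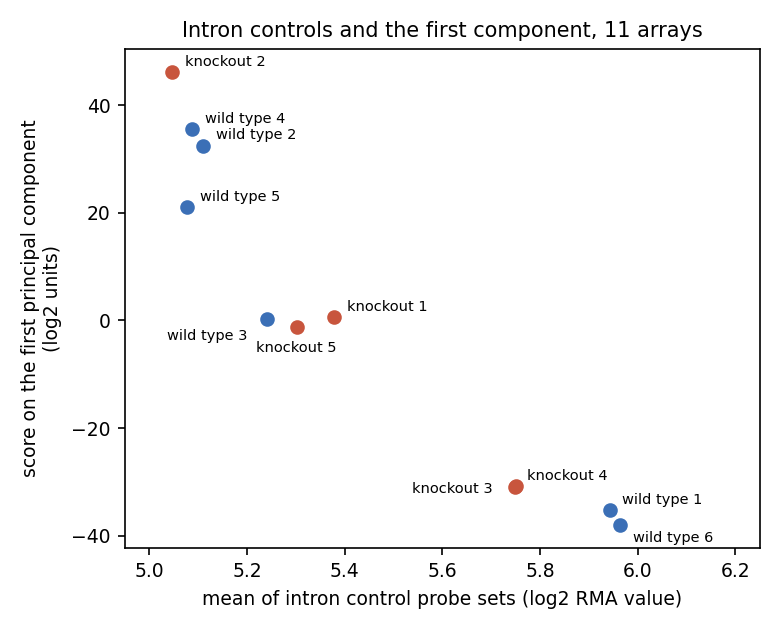
Score on the first principal component (vertical axis, log2 units) against the mean of the intron control probe sets (horizontal axis, log2 level) for 6 wild type (blue) and 5 knockout (red) arrays. Wild type arrays 1 and 6 and knockout arrays 3 and 4, the last pair nearly coinciding, had scores of -30.8 or below, and the others -1.26 or above.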

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

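The tests of the share of LSEC and of a single array in the patterns below were chosen after the result was seen. A sample counted as far from its group when its gap to the nearest other sample exceeded Dixon's 95% critical value, and chance flags about 1 in 20 groups, so 11.8 of the 236 groups tested, against 14 found. Wild type array 5 stood above the other wild type arrays for Ccl7 (9.05, others 8.09 to 8.40), Il6 (8.79, others 6.41 to 7.04), Spic (9.03, others 6.93 to 7.67), Vsig4 (9.14, others 7.24 to 7.70), Ugt2b5 (6.40, others 5.11 to 5.59) and the mean of the cytokine list (9.43, others 8.80 to 8.97). Knockout array 2 stood above the other knockout arrays for Atg13 (7.51, others 6.92 to 7.07) and for the mean of the cell cycle list (7.47, others 6.75 to 6.96). Knockout array 4 was highest for Atg5 (7.90, others 7.48 to 7.57) and knockout array 5 for Tfeb (9.04, others 8.78 to 8.85). Knockout array 3 was lowest for Vcam1 (11.38, others 11.96 to 12.08) and had the Y-linked mean of a male (8.02, others 3.42 to 3.62). A lysine biosynthesis spike-in control read 8.30 in wild type array 2 (others 5.69 to 6.14) and 8.24 in knockout array 3 (others 5.52 to 5.85).

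Macrophage markers were higher and hepatocyte markers lower in the knockout preparations. A lower share of LSEC, with the other cells in unchanged proportion, would raise both. The hepatocyte mean went the other way, which argues against that as the sole source. It was 9.35 ± 0.58 (SD, n = 6) in wild type and 8.47 ± 0.64 (SD, n = 5) in knockout, a difference of -0.88 (exact permutation p = 0.043, 0.23 adjusted over the lists). Within wild type, however, the macrophage and hepatocyte means rose together (r = 0.794, n = 6). Over all 11 arrays r was 0.009, but that value takes in the opposite differences between the genotypes. An r within knockout was not computed, and knockout array 2 was the highest of its group for both means (9.95 and 9.51). A share of LSEC that varied among the preparations therefore stays open. A single array is argued against, since the lowest median of the macrophage list with an array left out was 0.734. Macrophage RNA in varying amounts may contribute: within genotype the listed macrophage genes had a median pairwise r of 0.7995, against 0.149 at the 95th percentile of random lists. This shows that these genes varied together among the preparations, not what the difference between the genotypes comes from. Abundant ones were chosen after their values were seen. Of these, Cd5l (8.60 in wild type and 10.13 in knockout) and C1qb (8.88 and 9.76) met the study's rule, the latter not adjusted over the list alone (0.056). Slc40a1 (10.80 and 11.29, SE of the difference 0.46) did not. More macrophages in the knockout livers, a change in their state and a difference in isolation all stay open, since the isolation is not described in the sources used here and which listed genes LSEC express cannot be read from these samples; by number of lists chance cannot be excluded, as 12 of 100 splits, the real one counted, gave at least the real 15, with 19 the highest other.

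Genes that met the study's rule, cytokine genes among them, were higher or lower in knockout. RNA composition as seen in the intron controls was nearly even between the genotypes, which argues against it for the 8 called cytokine genes. The intron control mean was 5.40 ± 0.43 (SD) in wild type and 5.45 ± 0.30 (SD) in knockout (exact permutation p = 0.840). With this mean as a covariate the median log2 difference of the 8 was 0.96, and 0.94 without it. That adds little, as a covariate so balanced can hardly move the difference. Macrophage RNA in varying amounts could account for part of it: with the macrophage mean as a covariate the median was 0.44 (median SE 0.25) and 2 of 8 still met the rule, which a macrophage change caused by the genotype would give too. Within genotype the 123 higher clusters with a gene symbol (1 per symbol) outside the macrophage list had a median r of 0.671 with the macrophage mean (95th percentile of random sets 0.290), and the 57 such lower clusters outside the hepatocyte list 0.748 with the hepatocyte mean (95th percentile 0.199). For the rule, 23 of 100 splits, the real one counted, gave at least the real 228 (highest other 2013). Most of these splits divide the 4 arrays of highest intron signal unevenly. The real one has wild type arrays 1 and 6 on one side and knockout arrays 3 and 4 on the other. The share is therefore not the chance rate for splits balanced like the real one, and it neither excludes chance nor makes it likely. Among the other drawn splits that divide these 4 arrays evenly, the highest count was 350. Past an adjusted p of 0.05 the real count of 0 is met by all 100 splits whatever the data, so that comparison decides nothing. The highest other counts (3231 there) point to a structure of the samples.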

How the results depend on the processing

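Sex, the intron controls, both list means together, leaving out 4 arrays and the permutation of list means were chosen after seeing the data. Of the values for single genes under the alternatives 3013 stayed, 107 lost the rule, 63 gained it, 52 moved and 8 reversed. Genes called in neither fit that turned sign with a shift of no more than their SE are among the 3013. Those with a larger shift are the moved ones. Of the list medians 581 stayed, 24 moved by more than the SD of the list mean within genotype and 25 reversed. Only lists past camera on all arrays could count as reversed, so other medians that turned sign are among those that stayed or moved. Where the cause is not named, the cause was not tested. With an array left out, 0 to 1 clusters passed an adjusted p of 0.05 (1 without wild type array 5) and 8 to 16 lists passed camera (8 without knockout array 2), and the medians ran from -0.00875 to 0.134 for lysosome, from -0.0817 to 0.109 for cell cycle and from -0.0125 to 0.174 for oxidative phosphorylation. By the study's rule there were 123 clusters without variance moderation, 150 among clusters above the median level (fewer tested), 1247 at a fold of 1.2, 60 at a fold of 2 and 359 without the 4 arrays of highest intron signal. Of the lists 9 passed after repeated quantile normalization, 8 among clusters above the median level, and 0 with an estimated correlation, with fry and with the exact permutation of list means. With array weights the median was -0.0510 for cell cycle and -0.00426 for oxidative phosphorylation. With the hepatocyte mean as a covariate 29 clusters passed an adjusted p of 0.05 and 582 met the rule. With the macrophage mean as a covariate 18 clusters passed an adjusted p of 0.05, 1751 met the rule and 4 lists passed. Arg2 was then -0.0469, and the medians were -0.197 for lysosome, -0.00683 for NF-kB, -0.00844 for interferon-stimulated genes, -0.305 for antigen presentation, -0.128 for mesenchymal transition, -0.108 for basement membrane, -0.204 for cell cycle, -0.226 for oxidative phosphorylation, -0.129 for stellate cells and, by construction near 0, -0.122 for macrophage markers. With both means as covariates, whose difference separates the genotypes, leaving the genotype term poorly determined, 925 clusters met the rule and 3 lists passed. Atg5 was then -0.0258, Ugt2b5 0.234, Folr2 -0.0252, Tbx20 -0.151, Lamb1 -1.12, Serpina1b 0.195, Colec10 -0.710 and Abcc2 0.400. The medians were -0.0417 for lysosome, -0.00624 for cytokines, -0.128 for antigen presentation, -0.177 for mesenchymal transition, -0.240 for basement membrane, -0.00858 for cell cycle, -0.178 for oxidative phosphorylation, 0.0373 for hepatocyte markers, -0.0226 for macrophage markers and -0.710 for stellate cells. Levels below the antigenomic background mean of their array (4.67 to 5.17), as for Oas3 in all arrays, Aif1 in 4 wild type and Ugt2b5 in 4 knockout arrays, are not told apart from background.

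The replicate numbers gave no consistent sign of a pairing of the samples, which so few pairs cannot exclude. Correlations of same-numbered arrays after subtraction of group means were 0.006, 0.389, 0.079, -0.321 and 0.025. With the numbers as a block 250 clusters met the rule, 0 passed an adjusted p of 0.05 and 10 lists passed.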

Other observations

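The tests of intron-containing RNA and of genotype on the first component were chosen after the result was seen. The arrays parted along the first principal component. Genotype is argued against, with a difference in mean score of 5.92 against a range of at least 73.6 within each genotype (exact permutation p = 0.753). Varying amounts of intron-containing RNA or DNA may underlie it, as the intron control mean went with the component at r = -0.953 over 11 arrays and -0.895 within the 7 of lower signal, while the antigenomic background went the other way from the intron controls (r = -0.924). Genomic DNA in the extracts cannot be told apart from unspliced RNA. The mean of 1091 olfactory receptor clusters, silent in these cells, had r = 0.116 with the intron controls, and -0.073 without the 2 farthest arrays. That mean lay between 4.31 and 4.54, below the antigenomic background mean (4.67 to 5.17) in every array. A change in it is therefore hard to tell from background. Of the 100 splits, the 10 with the 4 arrays of highest intron signal on one side gave 106 to 2013 clusters by the study's rule and up to 3231 past an adjusted p of 0.05, and the other splits at most 1123 and 1.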
